A study of Homo sapiens with 6 samples.

How the data were processed

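RNA-seq libraries were made from total RNA, extracted with TRIzol, of the human renal cell carcinoma line 786-O. The labels name 6 libraries, 3 of cells that received the photosensitizer DTP without light (Dark) and 3 of cells that received as much DTP followed by light from a diode laser of 650 nm (PDT). DTP is a code name. Its concentration, the energy density and the time from irradiation to harvest are not given in the sources used here, and neither are the library kit, its strandedness, the aligner, the quantifier or the test behind the deposited p-values. The genome build is GRCh38 (hg38), per the submitters' processing notes. The labels do not say whether the libraries of a group came from separate cultures, so any spread behind the p-values may be technical, and how the test used the 6 libraries is not known here.

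The values came from one table of 20263 genes. Per the file headers, the authors deposited the mean TPM (a length-scaled share of all transcripts) of each group, a log2 fold change, a p-value and a q-value for each gene. The table used here has 0 columns of single libraries, so no SD, no depth per library and no refit could be had, and the only measure of error is the authors' deposited q-value. The deposited mean TPM values summed to 999941 in Dark and 999924 in PDT. The deposited log2 fold change was the log2 ratio of the mean TPM in PDT to that in Dark in every row, with a largest difference of 5.2e-11. Genes without signal are listed at 0.0001 TPM (4596 genes in Dark, 3997 in PDT and 3596 in both), and no fold is given against that floor. Among the 8457 genes with a deposited q-value under 0.05 and a p-value above 0, q was the p-value times 16006 over its rank in all 8457 within 1%, which is the Benjamini-Hochberg formula over 16006 genes. A p-value of 1 was listed for 3619 genes and a q-value of 0 for 70.

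The design fixed before the data were examined called for limma-trend and camera on single libraries. With group means alone, the authors' q under 0.05 took the place of the fit, over the 12359 genes with a mean over both groups of at least 1 TPM, and genes with an absolute log2 fold change of at least 1 were counted as 2-fold. "Rose" and "fell" are used of genes with a q under 0.05. The authors' p-values and the ratio of mean TPM need not share a scaling. For that reason the direction of a small fold is uncertain: 147 called genes had an absolute log2 fold change under 0.1, and 20 turned when the median log2 fold change (-0.04) was set to 0.

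Before the data were examined, 22 gene lists were fixed from textbook knowledge. Members were matched by symbol, 4 of them through an older symbol. For each list the members that rose, fell or were not called were counted, over all genes and after Benjamini-Hochberg adjustment over the list alone. Each list was compared with the other genes by the two-sided rank form of cameraPR (limma 3.58.1, R 4.3.3) on the log2 fold changes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 22 lists. A correlation could not be estimated from group means, so preset values of 0.05 and 0.1 were run in its place. The cameraPR test takes genes as its units and says nothing of the spread between libraries. As a description, the median of each list was placed among 10000 random lists of its size matched on mean TPM in 20 bins. In data simulated by shuffling the log2 fold changes of the PDT minus Dark comparison over its 12359 genes and shifting 200 of them, the test called 12% of 50 lists of 20 genes shifted by 0.25, 70% at 0.5, 100% at 1 and 100% at 2. It called 0.222% of 900 unshifted lists, and 3% of 200 unshifted lists lay outside the central 95% of matched random lists. Shuffling removes any correlation between the members of a list, so these rates hold for independent genes and not for lists of co-regulated genes.

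Named genes were chosen by a rule fixed before the data were examined: the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 TPM, the 2 called members of each list with the largest absolute change, and a few genes whatever their values, among them SREBF2, INSIG1, ABCA1 and HMOX1. Some genes that the rule gave are not reported here. The rule also asked for libraries of the groups that do not overlap, which could not be checked. Genes named beyond the rule were chosen after their values were seen. Of the 56 genes the rule gave, OSGIN1, IRF9 and CTSD share exon bases with another listed gene on their strand, and HSPA1A and HSPA1B, named beyond it, are near-identical copies, so reads could be split between genes in those cases. Positions, exon overlaps (bedtools 2.31.1), GC content and transcript length came from GENCODE 29 on GRCh38, the build of the deposited table, and 12351 of the 12359 genes had GC and length values. KEGG pathways were those written beside each gene in the deposited table, for pathways with 10 to 200 genes.

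Alternatives fixed before the data were examined were no filter, a filter of 5 TPM and pseudocounts of 0.1 and 0.01. Those added after seeing the data were a pseudocount of 1, q under 0.01, Bonferroni adjustment over 16006 genes, adjustment over the 12359 genes, the median set to 0, a loess trend on GC content and transcript length (span 0.3) taken out, the other preset correlations, and lists ranked by a signed z from the authors' p-value. Tables were handled with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 in Python 3.11.15.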

Results

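The transcriptome of 786-O cells, an established renal cell carcinoma line, was compared between 3 libraries of cells given the photosensitizer DTP in the dark (Dark) and 3 of cells given the same DTP concentration and then a 650 nm laser (PDT). A photosensitizer is a compound that, once excited by light, produces reactive oxygen species. The series title concerns DTP given with statins, which block cholesterol synthesis, so the comparison bears on how light-activated DTP changes the cells' transcripts and those of cholesterol metabolism among them. Both groups received DTP, and untreated, laser-only and statin-treated cells were not analysed here. Values are the authors' mean TPM of each group and their deposited comparison. The spread between libraries and the depth of each are unknown from this table, so no SD stands beside a mean.

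Most measured genes differed between irradiated and dark cells. Of 12359 genes with a mean of at least 1 TPM, 3724 rose and 4144 fell at q under 0.05 in the authors' deposited table, and 4491 were not called. Of the called genes, 939 rose and 503 fell at least 2-fold in the authors' deposited table. Among called genes with a mean of at least 5 TPM, the largest rises were in stress-induced transcription factors and a heat shock gene. In the authors' deposited table the mean TPM of FOS went from 0.600 in Dark to 149 in PDT (log2 fold change 7.96, q = 2.64e-141), that of FOSB from 0.562 to 59.9 (6.74), and that of HSPA6, an inducible HSP70, from 0.752 to 74.4 (6.63). The orphan nuclear receptors NR4A2 (0.468 to 42.3 TPM) and NR4A3 (0.529 to 37.4 TPM) followed in the authors' deposited table with log2 fold changes of 6.50 and 6.14. These folds start from Dark means under 1 TPM, and with 1 TPM added to both of the authors' deposited means they were 6.55 for FOS, 5.28 for FOSB, 5.43 for HSPA6, 4.88 for NR4A2 and 4.65 for NR4A3.

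Among the same genes the largest falls were in MT1E, a metal-binding metallothionein, from 809 to 54.1 TPM (log2 fold change -3.90, q listed as 0 in the authors' deposited table), and in CPA4, a carboxypeptidase, from 23.9 to 1.71 TPM (-3.80). ID3 and ID1, which inhibit helix-loop-helix transcription factors, fell from 272 to 24.6 TPM and from 529 to 60.9 TPM in the authors' deposited table (-3.47 and -3.12). POLR1G, a subunit of RNA polymerase I, fell from 52.5 to 7.26 TPM in the authors' deposited table (-2.86).

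**Figure D1:**
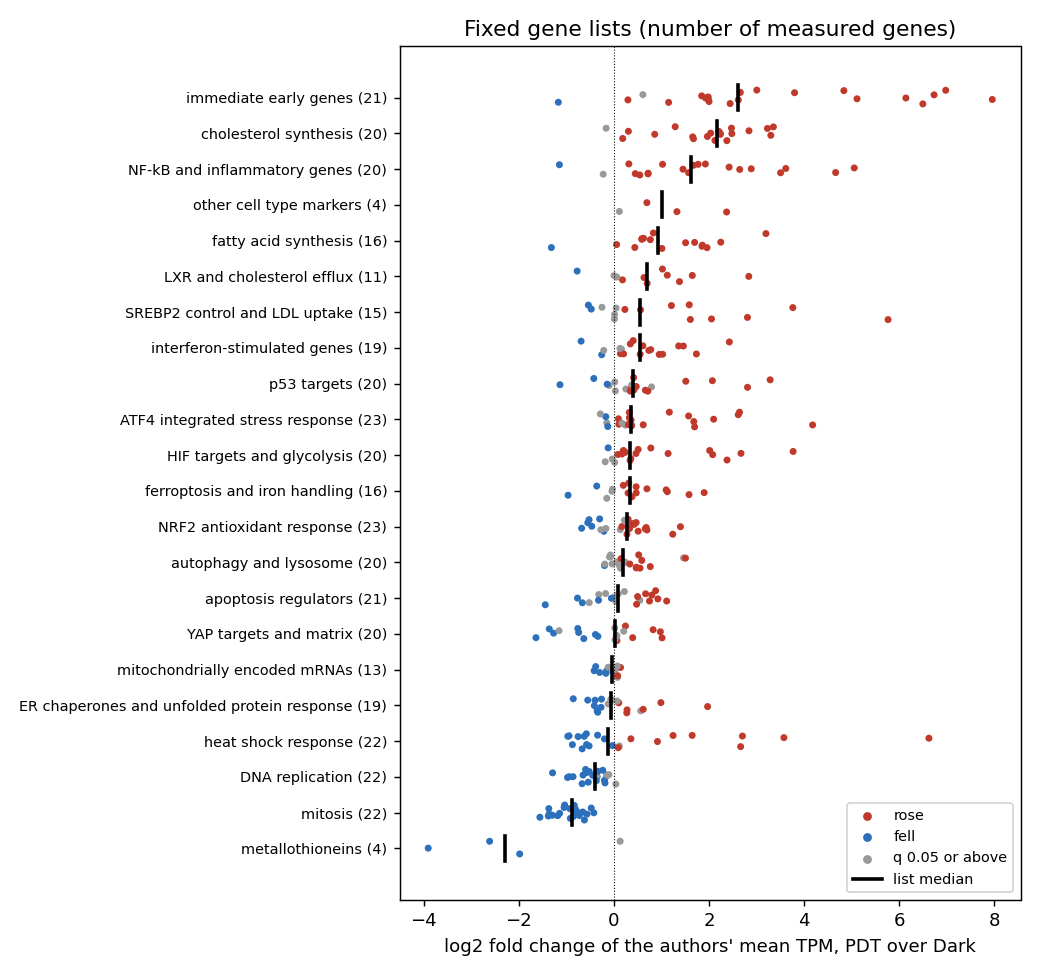
Log2 fold change of the authors' mean TPM, PDT over Dark (horizontal axis), for the members of each fixed gene list with a mean of at least 1 TPM (rows, with the number of genes). Points are genes, red where they rose and blue where they fell at q under 0.05, grey otherwise, and black bars are list medians, which run from 2.62 for the immediate early genes and 2.17 for cholesterol synthesis to -0.88 for mitosis and -2.30 for the metallothioneins.

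The enzymes of cholesterol synthesis rose almost without exception. All 20 listed genes were measured, and 19 rose and 0 fell by the authors' deposited table, with 19 called when adjusted over the list alone. HMGCS1, which makes HMG-CoA, rose from 47.1 to 482 TPM in the authors' deposited table (10.2-fold, q = 4.48e-207), and IDI1, the isomerase of isopentenyl diphosphate, from 32.2 to 318 TPM (9.86-fold, q listed as 0). The member not called, the sterol reductase TM7SF2 (named after its value was seen), had 5.79 TPM in Dark and 5.18 in PDT (q = 0.672 in the authors' deposited table). The list's median log2 fold change was 2.17, above each of 10000 random lists matched on expression, and the adjusted p of the rank test was 1.45e-08. KEGG steroid biosynthesis, tested after the values were seen, had 12 of 17 genes risen and 2 fallen in the authors' deposited table (adjusted p of 0.0120 by cameraPR, and 0.153 at a preset correlation of 0.05). Other KEGG pathways of this theme, likewise tested afterwards, did not pass: in terpenoid backbone biosynthesis 10 of 19 genes rose and 6 fell (adjusted p of 0.295 by cameraPR), and in cholesterol metabolism 10 of 26 rose and 7 fell (0.133), in the authors' deposited table.

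Of 15 measured genes that sense sterols and take up LDL, 9 rose, 2 fell and 4 were not called in the authors' deposited table, with 12 called when adjusted over the list alone. INSIG1, which retains SREBP precursors in the endoplasmic reticulum (ENSG00000186480, GRCh38 chromosome 7, 155297776 to 155310235), rose 13.6-fold, from 44.3 to 602 TPM (q = 2.95e-182 in the authors' deposited table). SREBF2, which encodes SREBP2 (ENSG00000198911, chromosome 22, 41833079 to 41907308), rose 3.05-fold, from 101 to 307 TPM, with q listed as 0 in the authors' deposited table. Among the members that fell was the site-2 protease gene MBTPS2, named after its value was seen (log2 fold change -0.47 in the authors' deposited table). The list's median was 0.56 and its adjusted p by cameraPR 0.0114, with an adjusted p = 0.0891 at a preset correlation of 0.1.

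Transcripts of cholesterol efflux, many of them targets of the oxysterol receptor LXR, rose as well: 8 of 11 measured genes rose, 1 fell and 2 were not called in the authors' deposited table, with 9 called when adjusted over the list alone. APOE, a lipid carrier, rose from 0.675 to 4.83 TPM in the authors' deposited table (log2 fold change 2.84, or 1.80 with 1 TPM added), and MYLIP, a ubiquitin ligase gene, from 11.1 to 34.8 TPM (1.65). ABCA1, the cholesterol exporter (ENSG00000165029, chromosome 9, 104781002 to 104928237), rose 2.60-fold, from 14.6 to 38.0 TPM (q = 2.30e-136 in the authors' deposited table). The gene that fell, named after its value was seen, was the cholesterol ester hydrolase gene NCEH1, from 107 to 62.8 TPM in the authors' deposited table. The list had a median of 0.70 and an adjusted p of 0.00875 by cameraPR, with an adjusted p = 0.0658 at a preset correlation of 0.1.

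Fatty acid synthesis genes rose in 15 of 16 cases in the authors' deposited table, and all 16 were called when adjusted over the list alone. The desaturase gene SCD rose 9.18-fold, from 135 to 1243 TPM, and the fatty acid synthase gene FASN 4.75-fold, from 108 to 514 TPM, both with q listed as 0 in the authors' deposited table. GPAM, which starts glycerolipid synthesis and was named after its value was seen, fell from 10.8 to 4.36 TPM in the authors' deposited table. The list's median was 0.92, above each of the 10000 matched random lists, with an adjusted p of 4.33e-05 by cameraPR and of 0.0107 at a preset correlation of 0.1. The matching KEGG pathways of fatty acids, tested after the values were seen, did not pass: fatty acid biosynthesis had 7 of 14 genes risen and 3 fallen (adjusted p of 0.318 by cameraPR), and biosynthesis of unsaturated fatty acids 9 of 23 risen and 5 fallen (0.214), in the authors' deposited table.

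**Figure D2:**
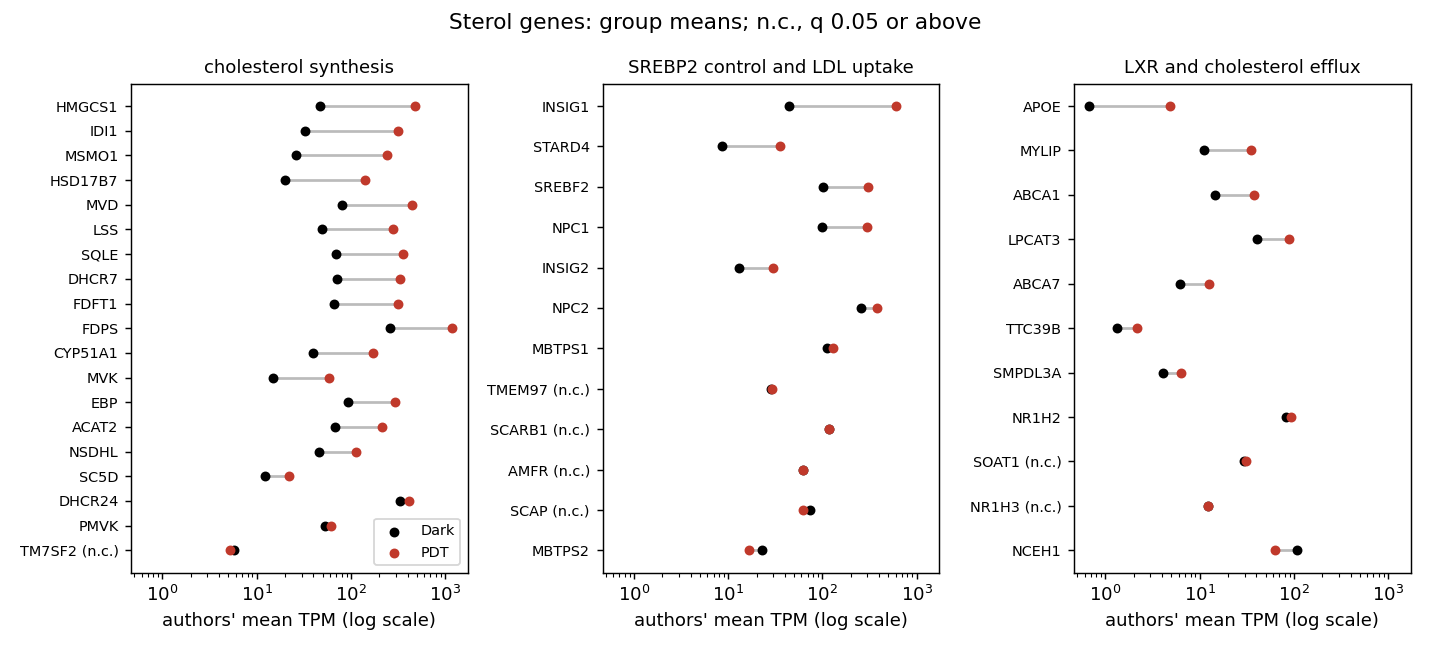
The authors' mean TPM (horizontal log axis) of measured members of the cholesterol synthesis, SREBP2 control and LDL uptake, and LXR and cholesterol efflux lists, black for Dark and red for PDT, joined by a grey line; "n.c." marks genes with q of 0.05 or above. Red lies to the right of black for the genes that rose, among them INSIG1 (44.3 to 602 TPM) and HMGCS1 (47.1 to 482 TPM).

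Immediate early genes, which respond to signals without new protein synthesis, rose with the largest median of any fixed list (2.62). Of 21 genes, 19 rose, 1 fell and 1 was not called in the authors' deposited table, with 20 called when adjusted over the list alone (adjusted p of the list 8.62e-09 by cameraPR). FOS, given above, led, and EGR3 went from 0.0325 to 4.11 TPM in the authors' deposited table (log2 fold change 6.98, or 2.31 with 1 TPM added). The AP-1 gene FOSL1, named after its value was seen, fell from 387 to 172 TPM in the authors' deposited table.

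Inflammatory genes controlled by NF-kB rose in 18 of 20 cases in the authors' deposited table, with 1 fall, 1 gene not called and 19 called when adjusted over the list alone. The chemokine gene CXCL2 rose 33.3-fold, from 8.05 to 268 TPM, and the cytokine gene IL6 25.4-fold, from 20.4 to 518 TPM, both with q listed as 0 in the authors' deposited table. TRAF1, named after its value was seen, fell from 2.62 to 1.18 TPM in the authors' deposited table. The median was 1.62 and the list's adjusted p 1.44e-06 by cameraPR. The KEGG NF-kappa B signaling pathway, tested after the values were seen, had 30 of 74 genes risen and 19 fallen in the authors' deposited table and did not pass (adjusted p of 0.318). Among interferon-stimulated genes the counts were 14 of 19 risen, 2 fallen (IFIT1 and OAS3, named after their values were seen) and 16 called when adjusted over the list alone by the authors' deposited table. ISG20, an exonuclease gene, rose from 0.932 to 5.02 TPM in the authors' deposited table (log2 fold change 2.43, or 1.64 with 1 TPM added), and IRF9, a transcription factor of interferon signalling, from 3.79 to 12.6 TPM (1.74). The interferon list's median was 0.55, with an adjusted p of 0.00179 by cameraPR and an adjusted p = 0.0649 at a preset correlation of 0.1.

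The heat shock list split. Of 22 genes, 9 rose and 12 fell in the authors' deposited table, 21 being called when adjusted over the list alone, and HSPA4L (-0.03), 1 of those that fell, turned when the median of all genes was set to 0. Beside HSPA6, the small heat shock gene CRYAB rose from 0.886 to 10.6 TPM in the authors' deposited table (log2 fold change 3.58, or 2.62 with 1 TPM added). Among genes named after their values were seen, the inducible HSPA1A and HSPA1B rose to 720 and 1328 TPM (2.67 and 2.70), while the abundant chaperones HSPA8, HSP90AA1 and HSPD1 fell by 0.75, 0.62 and 0.87 on the log2 scale in the authors' deposited table. The median was -0.11, the mean 0.59 and the direction of the rank test upward, with an adjusted p of 0.997 by cameraPR.

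Antioxidant genes of the NRF2 pathway rose in 13 of 23 cases and fell in 6 by the authors' deposited table, with 20 called when adjusted over the list alone. OSGIN1 rose 2.64-fold, from 21.5 to 56.7 TPM, and the aldo-keto reductase gene AKR1C3 2.36-fold, from 14.0 to 33.0 TPM in the authors' deposited table. HMOX1, the heme oxygenase gene (ENSG00000100292, chromosome 22, 35380361 to 35394214), rose 1.30-fold, from 47.1 to 61.4 TPM (q = 1.21e-06 in the authors' deposited table). Named after their values were seen, NQO1, GCLM and TXN fell by 0.46, 0.68 and 0.52 on the log2 scale in the authors' deposited table. The median was 0.28, and the list did not pass (adjusted p of 0.138 by cameraPR), but did with genes of at least 5 TPM (0.0371).

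Targets of ATF4, the factor of the integrated stress response, rose in 17 of 23 cases and fell in 2 in the authors' deposited table, with 20 called when adjusted over the list alone. ATF3, itself a stress transcription factor, rose 18.1-fold, from 8.92 to 162 TPM, and DDIT4, an inhibitor of mTORC1, 6.25-fold, from 437 to 2729 TPM in the authors' deposited table. The falls, named after their values were seen, were small: PSAT1 by 0.13 and VLDLR by 0.17 on the log2 scale in the authors' deposited table. The asparagine synthetase gene ASNS (118 TPM in Dark, 139 in PDT, q = 0.0602) and CHAC1, which encodes an enzyme that degrades glutathione (30.1 and 27.2 TPM, q = 0.389), also named afterwards, were not called in the authors' deposited table. The median was 0.36 and the adjusted p by cameraPR 0.000501, with an adjusted p = 0.0525 at a preset correlation of 0.1.

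Genes of endoplasmic reticulum chaperones and the unfolded protein response, taken as 1 list, went both ways. Of 19 genes, 6 rose and 8 fell in the authors' deposited table, with 15 called when adjusted over the list alone. DNAJB9 rose 3.92-fold, from 6.08 to 23.9 TPM, and HERPUD1, of ER-associated degradation, 1.99-fold, from 32.7 to 64.9 TPM in the authors' deposited table. The chaperone HSPA5 (BiP), named after its value was seen, fell from 577 to 434 TPM in the authors' deposited table. The list's median was -0.06, its mean 0.07 and the direction of its test upward, with an adjusted p of 0.961 by cameraPR.

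Targets of p53 rose in 11 of 20 cases and fell in 3 (TP53I3, XPC and AEN, named after their values were seen) in the authors' deposited table, with 15 called when adjusted over the list alone. BBC3, which encodes the pro-apoptotic PUMA, rose 9.76-fold, from 5.39 to 52.6 TPM, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, 7.02-fold, from 16.0 to 112 TPM (q = 5.14e-13 in the authors' deposited table). The median was 0.40 and the adjusted p by cameraPR 0.00656, with an adjusted p = 0.0891 at a preset correlation of 0.1. The KEGG p53 signaling pathway, tested after the values were seen, did not pass, with 20 of 60 genes risen and 18 fallen in the authors' deposited table (median 0.05, adjusted p of 0.687 by cameraPR). Among 21 apoptosis regulators, 8 rose and 5 fell in the authors' deposited table, with 13 called when adjusted over the list alone. BIRC5, the mitotic and anti-apoptotic survivin gene, fell from 127 to 46.7 TPM (log2 fold change -1.44), and the pro-apoptotic BMF rose from 3.36 to 7.27 TPM (1.11) in the authors' deposited table. Other members, named after their values were seen, went the other way. The anti-apoptotic MCL1 rose 1.39-fold and the pro-apoptotic BAK1 fell 1.58-fold in the authors' deposited table. That list's median was 0.09 and its adjusted p 0.308 by cameraPR.

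Mitotic genes fell without exception: 22 of 22 were lower in PDT at q under 0.05 in the authors' deposited table, and 22 when adjusted over the list alone. CENPE, a kinetochore motor, fell from 19.4 to 6.62 TPM (log2 fold change -1.55) and the kinesin gene KIF20A from 116 to 44.8 TPM (-1.38) in the authors' deposited table. The median was -0.88, below each of the 10000 matched random lists, with an adjusted p of 8.45e-09 by cameraPR. DNA replication genes fell in 17 of 22 cases and rose in 0 by the authors' deposited table, with 19 called when adjusted over the list alone. UHRF1, which maintains DNA methylation through replication, fell from 145 to 59.4 TPM (-1.29) and GINS1, of the replicative helicase, from 43.8 to 22.3 TPM (-0.97) in the authors' deposited table. The replication list's median was -0.41 and its adjusted p 0.000631 by cameraPR, with an adjusted p = 0.0525 at a preset correlation of 0.1. The matching KEGG pathways, tested after the values were seen, passed, but not at a preset correlation of 0.05. In cell cycle 77 of 138 genes fell and 26 rose in the authors' deposited table (adjusted p of 0.00818 by cameraPR, and 0.421 at 0.05). In DNA replication 27 of 35 fell and 2 rose (0.00818, and 0.235 at 0.05).

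HIF targets and glycolysis genes rose in 16 of 20 cases, and the glycolytic ENO1, named after its value was seen, fell by 0.12 on the log2 scale in the authors' deposited table, with 17 called when adjusted over the list alone. Other glycolytic members, likewise named afterwards, differed in size. HK2 rose 2.21-fold, PFKFB3 1.28-fold and ALDOA 1.06-fold, while PGK1 (q = 0.901) and LDHA (q = 0.572) were not called in the authors' deposited table. The glucose transporter gene SLC2A3 rose 13.7-fold, from 8.35 to 114 TPM, and NDRG1, a hypoxia-induced gene, 6.38-fold, from 81.0 to 517 TPM, both with q listed as 0 in the authors' deposited table. HIF targets named after their values were seen differed in size as well. ADM rose 4.22-fold, CA9 1.38-fold, BNIP3 1.18-fold and P4HA1 1.13-fold, while EGLN3 was not called (q = 0.760) in the authors' deposited table. The median was 0.35 and the adjusted p by cameraPR 0.000821, with an adjusted p = 0.0525 at a preset correlation of 0.1. The matching KEGG pathways, tested after the values were seen, did not pass: in HIF-1 signaling 27 of 71 genes rose and 22 fell (median -0.03, adjusted p of 0.532 by cameraPR), and in glycolysis and gluconeogenesis 10 of 42 rose and 17 fell (median -0.08, 0.785), in the authors' deposited table. Of 13 mitochondrially encoded mRNAs, 2 rose and 5 fell in the authors' deposited table, with 7 called when adjusted over the list alone. MT-CYB fell from 4290 to 3220 TPM and MT-ND2 from 3015 to 2316 TPM, while MT-CO1 and MT-CO2, named after their values were seen, rose by 0.08 and 0.14 on the log2 scale in the authors' deposited table. Their summed share was 6.50% of the authors' deposited TPM in Dark and 6.45% in PDT, and the list's adjusted p was 0.807 by cameraPR, with a median of -0.03 that turned to 0.02 when the median of all genes was set to 0.

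Autophagy and lysosome genes rose in 9 of 20 cases and fell in 1 (ATG12, named after its value was seen) in the authors' deposited table, with 10 called when adjusted over the list alone. WIPI1, of the early autophagosome, rose 2.84-fold, from 25.2 to 71.5 TPM, and the lysosomal protease gene CTSD 1.70-fold, from 1384 to 2354 TPM in the authors' deposited table. The median was 0.20 and the adjusted p by cameraPR 0.0198, with an adjusted p = 0.0692 at a preset correlation of 0.05 and 0.141 at 0.1. The KEGG pathway of animal autophagy, tested after the values were seen, had 39 of 115 genes risen and 31 fallen in the authors' deposited table and did not pass (median 0.0019, adjusted p of 0.318 by cameraPR). Genes of ferroptosis and iron handling rose in 11 of 16 cases and fell in 2 (NCOA4 and DHODH, named after their values were seen), with 13 called when adjusted over the list alone in the authors' deposited table. SAT1, of polyamine breakdown, rose 3.73-fold, from 82.2 to 307 TPM, and ACSL4, which activates polyunsaturated fatty acids, 2.99-fold, from 51.9 to 155 TPM in the authors' deposited table. Genes that protect from ferroptosis, named after their values were seen, rose too: GPX4 1.24-fold and GCH1 2.14-fold in the authors' deposited table. FTH1, FTL, SLC7A11 and HMOX1 are also in the NRF2 list, CHAC1 in the ATF4 list and LPCAT3 in the LXR list, so these lists are not independent. That list's median was 0.35 and its adjusted p 0.0248 by cameraPR, with an adjusted p = 0.0704 at a preset correlation of 0.05 and 0.141 at 0.1. KEGG ferroptosis, tested after the values were seen, had 12 of 31 genes risen and 7 fallen in the authors' deposited table and did not pass (adjusted p of 0.263 by cameraPR).

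YAP targets and matrix genes rose in 6 of 20 cases and fell in 8 in the authors' deposited table, with 14 called when adjusted over the list alone. THBS1, which encodes thrombospondin, fell from 359 to 115 TPM (log2 fold change -1.64) and the YAP target ANKRD1 from 42.3 to 16.5 TPM (-1.36) in the authors' deposited table. Of members named after their values were seen, the YAP target CTGF rose 1.97-fold and the matrix gene FN1 1.77-fold in the authors' deposited table. CYR61, likewise a YAP target, was not called (728 TPM in Dark, 738 in PDT, q = 0.218 in the authors' deposited table). The median was 0.02, the mean -0.22 and the direction of the test downward, with an adjusted p of 0.398 by cameraPR. Of 4 measured metallothioneins, 3 fell in the authors' deposited table and in 3 cases the call stood when adjusted over the list alone. MT2A fell 6.11-fold, from 2420 to 396 TPM, beside MT1E given above, while MT1F, named after its value was seen, had 18.1 TPM in Dark and 19.8 in PDT (q = 0.419 in the authors' deposited table). The list's median was -2.30 and its adjusted p 0.0272 by cameraPR, with an adjusted p = 0.0681 at a preset correlation of 0.1.

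Markers of other cell types (leukocytes, endothelium, stroma, normal kidney, liver, blood, glia and muscle) were mostly below 1 TPM. Of 22 listed, 4 reached that mean and 3 rose in the authors' deposited table, with 3 called when adjusted over the list alone. The monocyte marker CD14 went from 0.447 to 2.32 TPM (log2 fold change 2.37, or 1.20 with 1 TPM added) and the stromal marker PDGFRB from 0.707 to 1.77 TPM (1.33, or 0.70 with 1 TPM added) in the authors' deposited table. CD68, a lysosomal protein gene used as a macrophage marker and named after its value was seen, went from 47.5 to 76.9 TPM in the authors' deposited table. The list's median was 1.01, at the 97.1 percentile of matched random lists, with an adjusted p of 0.0238 by cameraPR, 0.0657 at a preset correlation of 0.1, 0.106 when ranked by signed z and 0.224 with genes of at least 5 TPM.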

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

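No paired analysis was possible because the table used here holds the authors' group means, which carry no replicate numbers. For the same reason other normalizations (relative log expression, totals), limma-voom, limma-trend, a count model, a fit on normalized columns, leaving out each library, the replicate block, fry and an estimated correlation were not run, and no other split of the libraries could be made. The settings named here other than the filters and the pseudocounts of 0.1 and 0.01 were chosen after seeing the data. The count of 7868 genes past the threshold ranged from 6809 to 8527 under the other settings but was 4620 (2188 rises, 2432 falls) with Bonferroni adjustment, a stricter criterion by construction. The count of 1442 genes that also changed 2-fold ranged from 1063 to 2066, apart from 936 with the filter of 5 TPM, which leaves fewer genes. The share of rises among 2-fold calls was 65.1%, and 59.9% with that filter, 71.5% without a filter and 68.9% with the median set to 0. Of 22 lists, 16 passed, and 14 to 16 under the other settings, but 5 passed (4 up, 1 down) with a preset correlation of 0.1: cholesterol synthesis, fatty acid synthesis, immediate early genes, NF-kB genes and mitosis. A larger preset correlation widens the null by construction. Of the 336 values of named genes under other settings, 334 kept their direction and their side of the threshold. Few of these settings could have changed either. A pseudocount added to both means cannot turn a direction. The shift that set the median to 0 was smaller than each absolute log2 fold change of these genes. Removal of the GC and length trend alone left the direction free to change. The side of the threshold was tested anew by Bonferroni adjustment alone, which 54 genes passed and CD14 and PDGFRB did not. None of the 56 genes chosen by the rule reversed under these settings, whereas HSPA4L, named beyond it, turned with the median set to 0. Depth is unknown from these means, so no detection limit can be given for genes at the floor.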

Other observations

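The tests in this part on single-exon genes and on KEGG pathways, and the gene families, were chosen after the results were seen. Of 324 KEGG pathways, 55 passed the rank test of cameraPR after Benjamini-Hochberg adjustment (39 up, 16 down), and 5 did with a preset correlation of 0.05. The KEGG pathways of p53, HIF-1 and NF-kappa B signaling, glycolysis, autophagy, ferroptosis and fatty acid biosynthesis were among the 269 that did not pass. Genes that make ribosomes fell: in ribosome biogenesis 59 of 73 genes fell and 2 rose by the authors' deposited q (median log2 fold change -0.63, adjusted p = 2.99e-09, and 0.00831 with a preset correlation of 0.05). Among them the processome gene NOL6 fell from 82.6 to 28.8 TPM, the RNA acetyltransferase gene NAT10 from 52.8 to 20.7 TPM and the pseudouridine synthase gene DKC1 from 166 to 67.0 TPM in the authors' deposited table. Subunits of RNA polymerases I and III fell in 14 of 16 cases, and mitochondrial ribosomal proteins in 64 of 78 (median -0.50), whereas 37 of 82 cytosolic ribosomal protein genes rose and 13 fell (median 0.09) by the authors' deposited q. Nucleocytoplasmic transport (65 of 89 fell, adjusted p = 2.79e-05, and 0.0751 with a preset correlation of 0.05), the spliceosome (96 of 128 fell, 3.31e-05 and 0.148) and the proteasome (34 of 44 fell, 0.00119 and 0.152) went the same way by the authors' deposited q. The importin genes IPO4 and KPNA2 fell from 75.3 to 17.2 TPM and from 543 to 232 TPM in the authors' deposited table. Tubulin genes fell in 10 of 15 cases, TUBB4B from 2158 to 532 TPM, while TUBA1A rose from 227 to 349 TPM in the authors' deposited table.

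Complement and coagulation genes rose in 25 of 32 cases and fell in 2 by the authors' deposited q (adjusted p = 8.05e-05 by cameraPR, and 0.0382 with a preset correlation of 0.05). C3, the central complement component, rose from 29.9 to 206 TPM and CFB from 2.10 to 19.0 TPM in the authors' deposited table. In cytokine and receptor interaction 57 of 101 genes rose and 15 fell by the authors' deposited q (adjusted p = 8.20e-05, and 0.152 with a preset correlation of 0.05), among them the stress cytokine gene GDF15, from 11.4 to 493 TPM. Lysosome genes rose in 57 of 106 cases and fell in 13 by the authors' deposited q (adjusted p = 0.0142, and 0.425 with a preset correlation of 0.05), NEU1 from 55.0 to 171 TPM. The 3 measured ID genes all fell, ID2 from 67.8 to 19.3 TPM (q = 0.0189 in the authors' deposited table), and 10 of 12 KLF transcription factors rose.

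Across the 12351 genes with annotation, the log2 fold change followed GC content weakly (Spearman's rho 0.06 across genes, which are not independent replicates), with medians from -0.08 in the eighth of genes with the lowest GC content to 0.05 in that with the highest. The share of genes with a 2-fold rise went from 4.66% to 11.9% between those eighths. Whether GC bias in the rise of the cholesterol synthesis genes is a candidate explanation was tested by taking out a trend on GC content and transcript length: their median was then 2.20, against a highest value of 0.41 among 10000 random lists matched on mean TPM, which argues against GC content, length and expression level as its source. What stays open is the irradiation of DTP-loaded cells, which the design names, against light alone or a difference in handling between the groups, none of which these libraries separate.

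Histone genes of the HIST1 and HIST2 clusters rose while DNA replication genes fell. Of 29 measured, 18 rose, all at least 2-fold, and 0 fell by the authors' deposited q, with HIST1H2BK going from 54.1 to 130 TPM, HIST1H2BD from 8.12 to 36.0 TPM and HIST1H1C from 14.6 to 38.1 TPM in the authors' deposited table. Reads moved between near-identical copies would leave the total as it was, but the summed TPM of the 68 listed genes rose 2.78-fold, from 133 to 369. The 227 single-exon genes outside the clusters, of any length, had a median log2 fold change of -0.092 (95% interval -0.19 to 0.01). This argues against single-exon structure alone as the source of the rise. With the trend on GC content and transcript length taken out, the median of the histone genes was 1.46. Single-exon genes that are also short were not tested apart, so these values cannot decide on them. The histone median of 1.42 lay above the highest of 10000 random lists matched on mean TPM (1.00). Because the family was chosen after its values were seen, that place was partly given and cannot decide on low expression. A change in the histone transcripts with irradiation may underlie the rise, but a difference between libraries in how RNA without a poly(A) tail was captured stays open, since the library kit is not given in the sources used here.

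Some large differences in the authors' mean TPM came without a call. Of 569 genes with a mean of at least 20 TPM and a 2-fold difference, 15 had a q of 0.05 or above in the authors' deposited table, among them TOMM6 (222 TPM in Dark and 87.4 in PDT, q listed as 1), EIF3F (166 and 55.9 TPM, q = 0.884) and TXNL1 (16.6 and 62.9 TPM, q = 0.646). A candidate explanation is that reads are shared with an overlapping or same-named gene: 7 of the 15 had such a partner in the table, against 32 of the 554 called genes (odds ratio 14.1, 95% interval 4.08 to 47.7, two-sided Fisher's exact test p = 1.78e-05), so the values go with it for those 7. The other 8, EIF3F and TXNL1 among them, had no same-strand exon overlap with another listed gene and no shared symbol. Reads shared with genes on the other strand, unlisted genes or similar copies elsewhere were not checked. For these 8, such unchecked sharing stays open. Nor can a spread between the libraries of a group be told apart from a difference in how the authors' TPM and their test were computed. The reason is that 0 columns of single libraries were at hand.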
